A study of Mus musculus with 4 samples.

How the data were processed

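RNA was measured in single cells of mouse hearts by droplet sequencing in 4 libraries, 1 for each combination of genotype and treatment, with 16000 cells loaded and 10000 targeted per library. Per the labels, the control hearts carry Tcf21-MerCreMer, a tamoxifen-inducible Cre recombinase at the Tcf21 gene, and the other hearts carry Tcf21-MerCreMer together with a floxed allele. The labels do not say which part of Tcf21 is floxed or how many animals went into a library, so these libraries are called the deletion-labelled libraries. The deposited files hold raw UMI counts per gene and cell barcode, which the authors made with Cell Ranger 5.0.1 on mm10, with cell barcodes already selected. A UMI count is the number of distinct RNA molecules read for a gene in a cell. Each feature list names 32287 features, of which 2 are added sequences, eGFP and MerCreMer.

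The library without infarction held 55710468 UMIs over 9149 barcodes in the control and 88509231 UMIs over 11541 barcodes in the deletion-labelled heart. The infarction libraries held 129704045 UMIs over 10203 barcodes in the control and 127757911 UMIs over 10873 barcodes in the deletion-labelled heart. Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs. These filters removed 205 and 367 barcodes without infarction and 250 and 544 after infarction, control first. Possible doublets were then removed by a score from simulated cell pairs, at an assumed rate of 0.8% per 1000 barcodes, which took out 655, 1032, 812 and 898 barcodes, with the libraries without infarction first and the control first in each pair. The kept cells numbered 8289, 10142, 9141 and 9431 in that order, with medians of 4260, 5715, 5368 and 5435 UMIs and of 1875, 2334, 1885 and 1951 genes per cell.

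All 4 libraries were clustered together on 2000 variable genes, 30 components and 20 neighbours with the Leiden method at resolution 1.0, with no correction for library. A cluster took the class whose markers were found in more of its cells than of all other cells by the highest mean difference in share, provided that this difference was at least 0.1 and at least 3 of the markers were found in 20% of its cells. It stayed unnamed when another class had at least 2 more markers than its own among the top 10 genes, or when its cells were shallow and no marker of its own was among them. The marker lists were written before the data were examined, while these naming limits were set after the data had been seen. The condition on markers of another class was first written as any more markers. It was loosened after it left a fibroblast cluster unnamed at the stricter mitochondrial limit, and the names at the reported settings are the same under both versions. Of 34 clusters, 30 received names in 11 classes and 4 stayed unnamed.

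UMIs were summed over the cells of each class in each library and expressed as CPM, the counts of a gene per 1000000 UMIs of the class sum. Fibroblasts were the main class, and mononuclear phagocytes, neutrophils, endothelial cells and mural cells were compared between genotypes as well. Each library pair was compared by the log2 ratio of CPM. Its 95% interval is the exact Clopper-Pearson interval conditional on the sum of both counts, shares of cells carry exact Clopper-Pearson intervals, and CPM values carry exact Poisson intervals. All of these intervals cover counting error only, because each group has 1 library and the spread between animals is unknown, so no test was run, no p-value is given and genes that differ are not counted across the genome. No paired analysis was possible because each group has 1 library. Counts under 3 UMIs in a class sum were raised to a floor of 3 UMIs in every ratio, while the intervals of single genes use the counts as read. A ratio against 0 UMIs is a lower bound.

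For 33 gene lists, the median log2 ratio was taken over members with at least 10 UMIs in either sum, with an interval from 1000 Poisson redraws of the counts. Members were counted as higher or lower when CPM differed by at least 1.5-fold, a rule of size and not a test. The percentile of each median was found among 10000 random lists matched for expression. Members whose level in the class was under a ratio of 0.1 to their level in another class of at least 50 cells were marked as possible free RNA. Ddit3, Aldoa, Ccl19 and Ccl21a have more than 1 identifier each and were left out of the lists, Mx1 is absent from the feature list, and Nov, Wisp2 and Sepp1 were read as Ccn3, Ccn5 and Selenop.

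Genes named singly were the 10 with the highest and the 10 with the lowest log2 ratio in fibroblasts in each of 4 comparisons. They were the 5 each way in the other classes in both genotype comparisons, the 5 each way for the difference of the genotype log2 ratios, and 2 each way per list. The single genes came from those with at least 50 CPM and at least 30 UMIs in at least 1 of the 2 class sums that were not marked as possible free RNA. Mitochondrial, ribosomal protein, haemoglobin, Y-linked and unnamed predicted genes, with Xist and Tsix, were left out of them. Some genes that these rules select are not given in the text. This rule, the gene lists and the comparisons were chosen before the data were examined. The share of cells with a UMI was taken after thinning each cell to 2000 UMIs.

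The alternatives tried were median of ratios scaling, CPM without mitochondrial, ribosomal and haemoglobin genes, the mean of CPM per cell, no low-count filter, possible free RNA left out, no doublet removal, at most 10% mitochondrial UMIs, at least 500 genes, resolutions of 0.5 and 2.0, each library clustered alone, non-immune cells as the denominator, no thinning and thinning to 1000 UMIs. Chosen after seeing the data were the activated fibroblast cluster alone and the lists of clock and glucocorticoid-induced genes. So was a 50% cutoff beside the 80% cutoff for clusters of the baseline type. A separate run of the first naming rule at the stricter mitochondrial limit was added after that rule had been loosened. Counting intervals and list medians were computed on simulated Poisson counts with set ratios, as a check of the computation only. After allowing for the shift of the totals, intervals of genes set at 2-fold held the set ratio for 95.5% of genes in both genotype comparisons. Intervals of genes set at 4-fold in the infarction libraries held it for 89.4%. A list of 30 genes set at 2-fold gave medians of 0.97 and 0.98 on the log2 scale. The simulation held no doublets, free RNA or spread between cells or animals. The analysis ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9.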

Results

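Single live nucleated cells sorted from mouse hearts were sequenced in 4 libraries, 1 per group, without replicates. The groups were control and deletion-labelled hearts without infarction, and control and deletion-labelled hearts 3 days after myocardial infarction, which kills part of the heart muscle by loss of its blood supply. Per the labels all hearts received tamoxifen, and the design of the series states that TCF21, a transcription factor of cardiac fibroblasts, was deleted in those cells. The libraries held between 55710468 and 129704045 UMIs. Xist, the transcript of the inactive X chromosome, had 16, 10, 12 and 15 UMIs in the libraries in the order given above, and the Y-linked Ddx3y had 5603, 8859, 7813 and 8984.

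Tcf21 (ENSMUSG00000045680, mm10 chromosome 10, 22817281 to 22820174, minus strand) was higher, not lower, in the fibroblasts of the deletion-labelled libraries. Without infarction it stood at 147 CPM (142 to 151; 4039 UMIs) in the deletion-labelled library and at 95.5 CPM (91.3 to 99.8; 1947 UMIs) in the control, a 1.54-fold difference and a log2 ratio of 0.62 (0.54 to 0.70). After infarction it stood at 32.6 CPM (30.7 to 34.5; 1151 UMIs) against 22.3 CPM (20.7 to 24.0; 706 UMIs), a 1.46-fold difference and a log2 ratio of 0.54 (0.41 to 0.68). Against the library of the same genotype without infarction, Tcf21 was 4.28-fold lower in the control infarction library, with a log2 ratio of -2.10 (-2.22 to -1.97), and 4.51-fold lower in the deletion-labelled one, with a log2 ratio of -2.17 (-2.27 to -2.08). Fibroblasts with a Tcf21 UMI after thinning to 2000 UMIs made up 16.8% (15.1 to 18.5) of the control and 21.9% (20.1 to 23.8) of the deletion-labelled library without infarction, and 4.68% (3.43 to 6.21) and 7.92% (6.58 to 9.43) after infarction. Between 14 and 27 shallower fibroblasts per library were left out of these shares, and without thinning the shares were 53.9%, 70.8%, 37.4% and 39.6%. In endothelial cells, which lack Tcf21, the thinned shares were 0.449%, 0.418%, 0% and 0%, where 0 of 193 and 0 of 447 cells have upper bounds of 1.89% and 0.822%. The median depth before thinning was 10475, 13378, 31384 and 19725 UMIs in fibroblasts and 3580, 5160, 8072 and 4830.5 in endothelial cells. Reads of this assay come from the 3' end of transcripts and the labels do not name the floxed part, so UMIs of Tcf21 may come from a transcript that lacks it. In the fibroblast cluster that held most fibroblasts of both infarction libraries, examined after the data were seen, the log2 ratio of Tcf21 between the infarction libraries was -0.037.

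**Figure D1:**
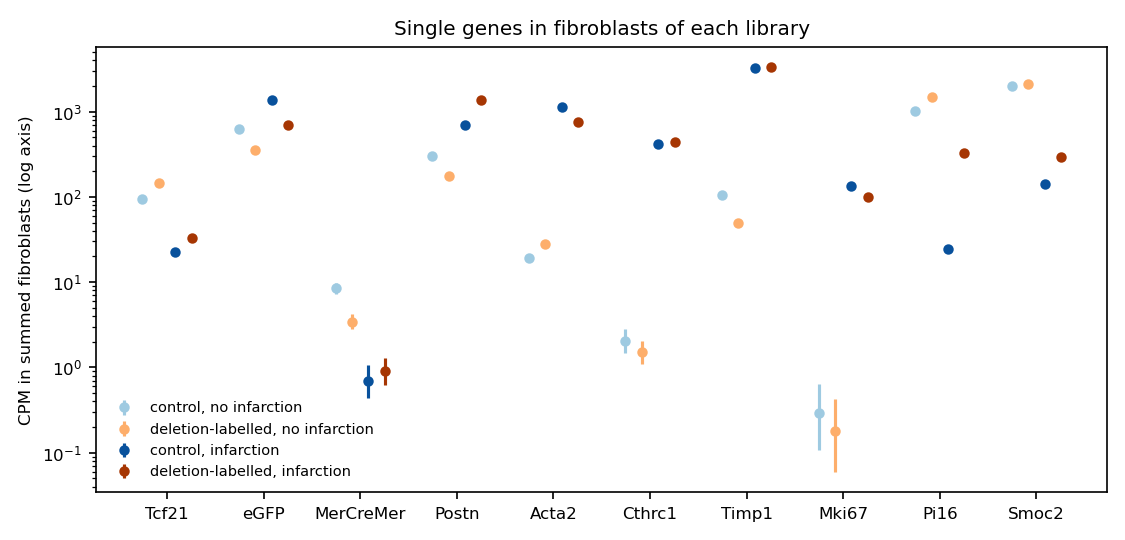
CPM of 10 genes in the summed fibroblasts of each of the 4 libraries on a log axis, with bars for the 95% Poisson interval. Tcf21 stands at 95.5 and 147 CPM without infarction and at 22.3 and 32.6 CPM after infarction, control first.

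The cellular make-up of the hearts was compared first. Without infarction endothelial cells, the lining of blood vessels, were the most frequent class, at 51.3% (50.2 to 52.4) of control and 50.4% (49.5 to 51.4) of deletion-labelled cells. At 3 days after infarction the same class made up 2.44% (2.13 to 2.78) and 5.34% (4.90 to 5.82), and neutrophils, the first leukocytes to enter injured tissue, made up 37.2% (36.2 to 38.2) and 34.9% (33.965 to 35.9) against 0.398% and 1.02% without infarction. Mononuclear phagocytes, the monocytes and macrophages, made up 30.9% (29.9 to 31.8) and 25.3% (24.4 to 26.2) after infarction against 6.50% and 3.92% without. Fibroblasts, the cells that make the collagen matrix, were 23.0% (22.1 to 23.9) and 19.9% (19.1 to 20.6) of cells without infarction and 10.7% (10.1 to 11.4) and 15.7% (14.95 to 16.4) after it, control first in each pair.

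Other classes differed in the same tables. Dendritic cells were 0.241% and 0.168% of cells without infarction and 5.80% and 4.60% after it, and T and NK cells were 1.34% and 0.661% against 3.57% and 3.81%. B cells were 4.71% of the control and 1.60% of the deletion-labelled cells without infarction, and 6.29% and 5.13% after it. Mural cells, which wrap blood vessels, were 2.36% of control and 5.42% of deletion-labelled cells without infarction and 0.842% and 1.83% after it. Lymphatic endothelial cells were 0.688%, 0.345%, 0.197% and 0.138%, and cardiomyocytes 0.169%, 0.276%, 0.109% and 0.265%, in the same order. Unnamed clusters held 9.24%, 15.97%, 1.88% and 2.97%. Without infarction most of these cells lay in clusters 7 and 13, where the endothelial markers scored highest. These clusters held 430 and 315 control and 1022 and 583 deletion-labelled cells. Cluster 7 stayed unnamed for low depth and cluster 13 for cardiomyocyte genes at its top. The near equality of the endothelial shares without infarction therefore depends on the naming limits. Shares sum to a whole, so a share can differ because another class does: among named non-immune cells alone fibroblasts were 29.6% and 25.9% without infarction and 74.6% and 67.3% after it, which turns the order of the infarction libraries and that of the treatments. Unnamed clusters, with clusters 7 and 13 among them, were left out of this denominator.

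**Figure D2:**
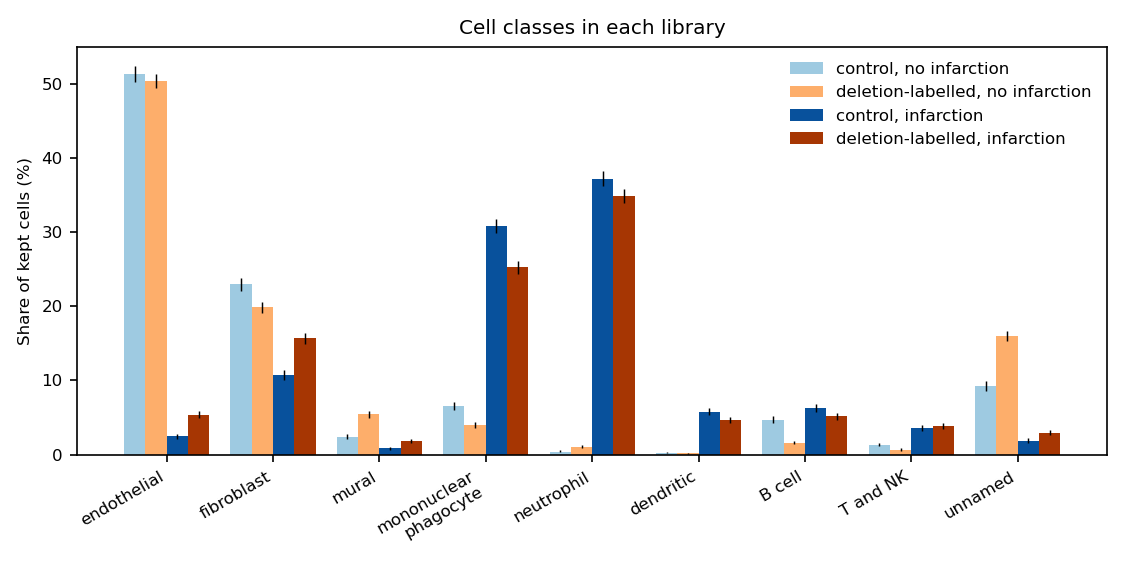
Share of kept cells in percent for 8 classes and the unnamed clusters in each of the 4 libraries, with bars for the exact 95% interval. Endothelial cells are at 51.3% and 50.4% without infarction and at 2.44% and 5.34% after it.

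Deletion-labelled and control fibroblasts were compared first in the uninjured heart. Mmp3, a secreted protease that degrades matrix, was 24.1-fold lower in the deletion-labelled library, at 8.39 against 203 CPM, with a log2 ratio of -4.59 (-4.79 to -4.40). Nr1d1 and Nr1d2, transcriptional repressors of the circadian clock, were 5.41-fold and 4.05-fold lower. Angptl7, a secreted matrix-associated protein, was 3.12-fold higher, at 88.4 against 28.3 CPM, with a log2 ratio of 1.64 (1.51 to 1.78), and Mfap4, an elastic fibre protein, was 2.25-fold higher, with a log2 ratio of 1.17 (1.11 to 1.23). Fibroblast clusters 2 and 8 held most of the class in both libraries, with 1367 and 504 cells in the control and 1490 and 489 in the deletion-labelled library.

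Among the other genes named in this comparison, Rnaset2a and Rnaset2b, ribonucleases of lysosomes, had log2 ratios of 1.27 and 1.23. Ifit3, an interferon-induced gene, had 1.03, and the transcription factor Sox4 had 0.99. Igfbp5, which binds insulin-like growth factors, had 0.96, Bloc1s1 had 0.92 and Clec3b, the secreted protein tetranectin, had 0.91. On the lower side Zc3hav1, an antiviral protein, stood at -2.49, the transcription factor Zbtb16 at -2.40 and Syne2, a nuclear envelope protein, at -1.54. The neutrophil-attracting chemokine Cxcl5 stood at 18.5 against 52.1 CPM, Galnt15 at -1.36, the complement component C7 at -1.33 and the flavin monooxygenase Fmo2 at -1.31.

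Most lists of fibroblast identity and matrix genes lay near 0 in this comparison. Of 30 resident fibroblast genes 2 were at least 1.5-fold higher and 3 lower, with a median log2 ratio of 0.09 (0.08 to 0.10); Mfap4 stood at 1.17 and Fmo2 at -1.31. Of 29 myofibroblast and contractile genes 2 were higher and 3 lower, with a median of -0.03 (-0.12 to 0.01) that was -0.30 without members marked as possible free RNA; Tnc, a matrix protein of injured tissue, stood at -1.71 and the collagen cross-linker Lox at -1.36. No member of the 17 fibrillar and network collagens passed 1.5-fold, with a median of -0.18 (-0.21 to -0.15). Col1a2 stood at 0.13 and Col4a2 at -0.56. Of 20 genes of collagen processing and cross-linking 2 were lower, with a median of -0.08. Of 30 matricellular and glycoprotein matrix genes 3 were higher and 7 lower, with a median of -0.10; Timp1, an inhibitor of matrix proteases, stood at -1.10. Of 22 TGF-beta ligands, receptors and targets 2 were higher and 3 lower, with a median of -0.12, and Id3 stood at 0.75. Of 12 complement genes 4 were lower, with a median of -0.24, and of 16 Wnt pathway modulators 1 was higher and 4 lower, with a median of -0.16. Of 29 chemokines, cytokines and acute phase genes 1 was higher and 6 lower, with a median of -0.10 and Saa3, an acute phase protein, at -2.72.

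Lists of interferon, mitochondrial and secretory genes were farther from 0. Of 31 interferon-stimulated genes 13 were higher and 0 lower, with a median of 0.55 (0.45 to 0.62) above the 10000 random lists; Ifi44 stood at 1.80 and Oas2 at 1.46. Of 36 nuclear genes of the mitochondrial respiratory chain 2 were higher by 1.5-fold and 34 were within it, with a median of 0.41 (0.37 to 0.42), and Cox6c stood at 0.64. Of 23 genes of the secretory pathway and ER stress 7 were lower and 0 higher, with a median of -0.42 (-0.47 to -0.39). Hspa5, the main chaperone of the endoplasmic reticulum, stood at 732 against 1452 CPM with a log2 ratio of -0.99, and Hyou1 at -1.05. Of 18 tendon and cartilage type genes 6 were higher and 1 lower, with a median of 0.36 (0.18 to 0.41); Cilp2 stood at 1.55. Of 10 epicardial genes 5 were lower and 0 higher, with a median of -1.23 (-1.45 to -0.57) that was -0.25 without doublet removal and -0.23 with each library clustered alone; Upk3b and Msln had 0 UMIs against 36 and 35 and were at least 16.2-fold and 15.7-fold lower. The medians were 0.32 for 19 mural and smooth muscle genes, of which 18 were marked as possible free RNA, 0.12 for 16 adipocyte and lipid genes, which was -0.0044 without possible free RNA, and 0.01 for 29 dissociation and immediate-early genes. They were 0.06 for 25 glycolysis and hypoxia genes, -0.03 for 28 S-phase genes and -0.05 for 27 G2 and M-phase genes, the last of which was 1.63 without doublet removal. Genes of other cell types read in fibroblasts had medians of 1.15 for 11 cardiomyocyte genes, 0.27 for 12 endothelial genes and -0.32 for 16 leukocyte genes. The median over all 3548 genes with enough UMIs was -0.06.

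The same comparison was made between the fibroblasts of the injured hearts. Genes of resident fibroblasts were higher in the deletion-labelled library: 26 of 30 by at least 1.5-fold and 0 lower, with a median log2 ratio of 1.45 (1.41 to 1.52), or 2.73-fold. Apod (ENSMUSG00000022548), a secreted lipid-binding protein, was 25.5-fold (21.3 to 30.8) higher, at 99.3 against 3.89 CPM. Clec3b was 23.3-fold higher and Pi16, a marker of adventitial-type fibroblasts, was 13.6-fold higher, with log2 ratios of 4.54 and 3.76 (3.65 to 3.87). The fibroblasts of the 2 libraries were spread differently over the clusters: cluster 5 held 949 of 980 control and 907 of 1479 deletion-labelled fibroblasts, and clusters 2 and 8 held 7 and 22 control against 233 and 339 deletion-labelled cells. Within cluster 5 alone, which was chosen after the cells per cluster had been seen, the median of the resident genes was 0.48, Apod stood at 1.32, Clec3b at 2.76 and Pi16 at 2.02.

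Other named genes on the higher side were the matrix protein Tnxb at a log2 ratio of 3.37, the actin-severing protein Gsn at 3.28, the transporters Abca8b and Abca8a at 3.07 and 2.56, the protease Htra3 at 2.41, the ectonucleotidase Entpd2 at 2.30 and the surface glycoprotein Cd34 at 2.17. Within cluster 5 alone Tnxb stood at 0.92, Gsn at 0.87 and Cd34 at 1.08. On the lower side were the histone genes Hist1h2ap at -1.80 and Hist1h1b at -0.92, the replication and cell cycle genes Mcm6 at -0.86 and Cdk1 at -0.81, and BC004004 at -1.52. Gstp1, a glutathione transferase, stood at -1.08, Mmp3 at -1.02, Mpp6 at -0.95, the fatty acid binding protein Fabp5 at -0.92 and the growth factor Hbegf at -0.81.

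Most myofibroblast genes were within 1.5-fold in this comparison. Of 29 myofibroblast and contractile genes 2 were higher and 4 lower, with a median of -0.28 (-0.31 to -0.22), below all 10000 random lists, and a median of -0.10 within cluster 5 alone. Acta2, the smooth muscle actin of myofibroblasts, stood at 754 against 1126 CPM, while Postn, a matrix protein of activated fibroblasts, stood at 1381 against 691 CPM. Scx, a tendon transcription factor, stood at 1.66 and the contractile gene Cnn1 at -0.90. Of 17 collagens 2 were higher, with a median of 0.27 (0.25 to 0.30). Col6a2 stood at 413 against 219 CPM and Col6a1 at 520 against 279 CPM, while Col1a1 stood at 3504 against 3441 CPM. Of 30 matricellular and glycoprotein matrix genes 13 were higher and 2 lower, with a median of 0.43 (0.42 to 0.47); Thbs4 stood at 1.99 and Fbln1 at 1.70. No gene of collagen processing and cross-linking passed 1.5-fold, with a median of 0.032 over 20 genes that was -0.021 with median of ratios scaling and -0.088 with the mean of CPM per cell.

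Of 12 complement genes 8 were higher in the deletion-labelled infarction library and 0 lower, with a median of 1.47 (1.41 to 1.54); C7 stood at 17.4 against 0.822 CPM and C4b at 24.1 against 5.66 CPM. Of 18 tendon and cartilage type genes 11 were higher and 0 lower, with a median of 1.18 (0.93 to 1.5) and Angptl7 at 3.28. Within cluster 5 alone both medians were lower, at 0.22 and 0.44. Of 40 G2 and M-phase genes 16 were lower and 0 higher, with a median of -0.55 (-0.58 to -0.51) and Aurkb, a mitotic kinase, at -0.91. Of 30 S-phase genes 6 were lower and 0 higher, with a median of -0.48 (-0.51 to -0.42) and Exo1 at -0.94. Within cluster 5 alone the medians were -0.25 for G2 and M-phase genes and -0.22 for S-phase genes. Of 12 epicardial genes 8 were lower and 2 higher, with a median of -2.87 (-3.38 to -2.13) that was -1.92 without doublet removal; Krt8 had 0 against 132 UMIs and was at least 49.2-fold lower, while Sema3d stood at 1.56.

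The remaining lists of this comparison had smaller medians or held genes of other cells. Of 22 TGF-beta genes 5 were higher and 1 lower, with a median of 0.045 that was -0.0081 with median of ratios scaling; Tgfbr3 stood at 1.05 and Id3 at -0.54. Of 31 interferon-stimulated genes 4 were higher and 1 lower, with a median of 0.26 and Ifi27l2a at 1.34. The medians were 0.23 for 18 Wnt modulators, of which 4 were higher and 4 lower, -0.02 for 29 chemokines, cytokines and acute phase genes, 0.29 for 15 adipocyte and lipid genes and 0.25 for 29 dissociation and immediate-early genes. They were -0.16 for 25 glycolysis and hypoxia genes, -0.044 for 36 respiratory chain genes, -0.10 for 23 secretory pathway genes and -0.43 for 20 mural and smooth muscle genes. Genes of other cell types had medians of 0.92 for 12 endothelial genes, -0.28 for 16 leukocyte genes and 1.46 for 12 cardiomyocyte genes, the last of which was -1.47 with each library clustered alone. At the stricter mitochondrial limit with the naming rule first written, the main cluster of infarction fibroblasts stayed unnamed, and the medians of the resident genes, the collagens and the matricellular genes were 0.69, -0.44 and -0.24. The median over all 3111 genes with enough UMIs was -0.05.

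**Figure D3:**
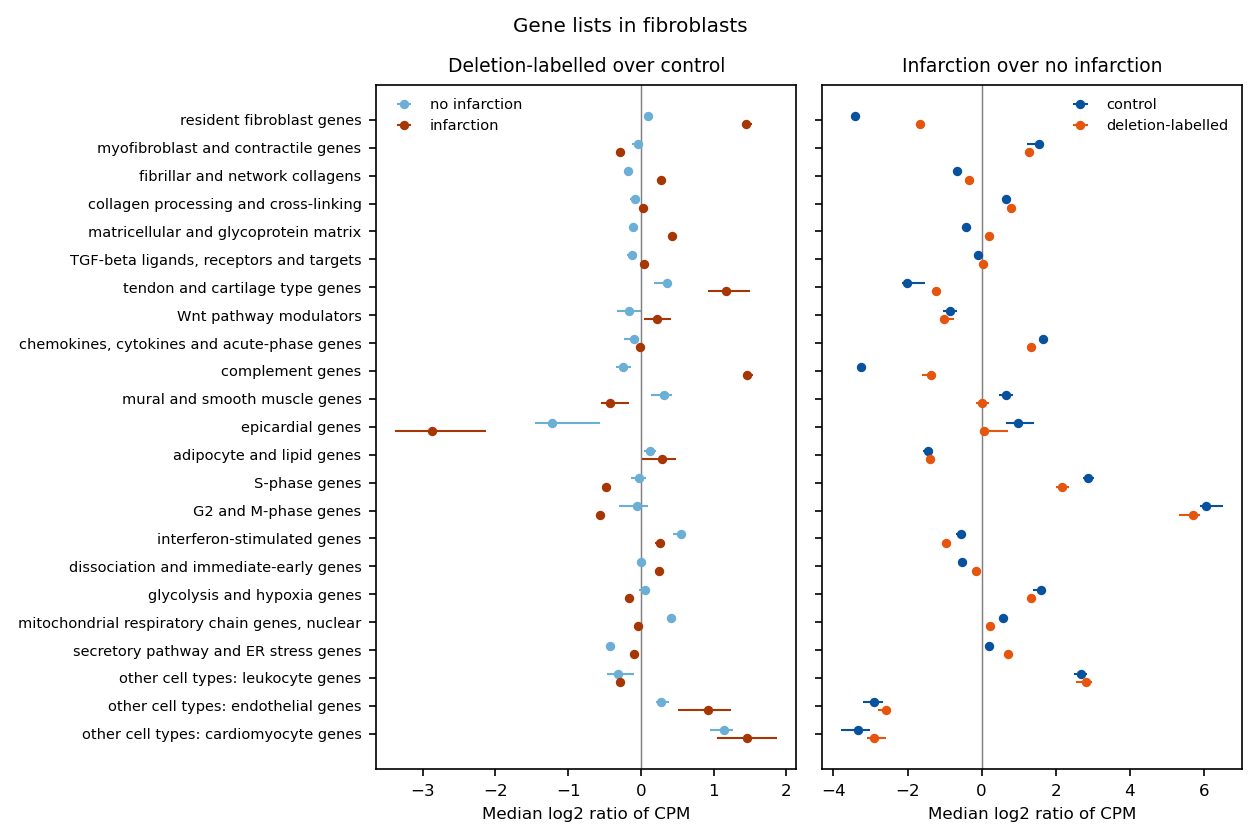
Median log2 ratio of CPM for the gene lists measured in fibroblasts, for the deletion-labelled over the control library on the left and infarction over no infarction on the right, with bars for the 95% interval from redrawn counts. Resident fibroblast genes stand at 0.09 without and 1.45 with infarction on the left, and at -3.42 in controls and -1.67 in deletion-labelled hearts on the right.

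Infarction was compared with no infarction in the fibroblasts of the control hearts. Cell division genes were higher: all 40 G2 and M-phase genes by at least 1.5-fold, with a median log2 ratio of 6.07 (5.90 to 6.52), or 67.1-fold. Mki67, a marker of dividing cells, stood at 136 against 0.294 CPM. Genes of activated fibroblasts were higher too: Cthrc1, a secreted protein of activated fibroblasts, by 200-fold (148 to 278), at 412 against 2.06 CPM, and Acta2 at 1126 against 19.2 CPM with a log2 ratio of 5.88. Resident fibroblast genes were lower: 29 of 30 by at least 1.5-fold, with a median of -3.42 (-3.45 to -3.36), or 10.7-fold. Clusters 2 and 8 held most of the fibroblasts without infarction, and cluster 5 held 949 of the 980 after it.

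The genes named in this comparison on the higher side were led by Hmmr, a mitotic spindle gene, with 3331 UMIs against 1 and a log2 ratio of 9.48 (8.59 to 16.37). Cdca3 had 2107 UMIs against 0 and was at least 453-fold higher. Mki67 stood at 8.85, Ptprn at 8.78, Ccna2, a cyclin, at 8.66, Ube2c at 8.56, Pclaf at 7.68, Hist1h1b at 7.65 and Spc24 at 7.54. On the lower side Myoc stood at -9.16, the carboxylesterase Ces1d at -8.35, the methyltransferase Inmt at -8.13, C7 at -7.62 and the basement membrane collagen Col4a3 at -6.92. Clec3b stood at 12.0 against 1299 CPM, Efhd1 at -6.74, Hmcn2 at -6.63, the scavenger receptor Scara5 at -6.59 and Galnt15 at -6.59.

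Matrix lists held members on both sides. Of 30 myofibroblast and contractile genes 21 were higher and 2 lower, with a median of 1.56 (1.23 to 1.60), or 2.94-fold. Of 17 collagens 4 were higher and 9 lower, with a median of -0.67 (-0.72 to -0.62); Col1a1 stood at 3441 against 1465 CPM and Col12a1 at 2.52, while Col6a2 stood at -2.20. Of 20 genes of collagen processing and cross-linking 11 were higher and 2 lower, with a median of 0.65, P4ha3 at 6.13 and Lox at 522 against 44.7 CPM. Of 30 matricellular and glycoprotein matrix genes 9 were higher and 14 lower, with a median of -0.43; Timp1 stood at 3249 against 106 CPM and Ccn4 at 7.45. Of 22 TGF-beta genes 9 were higher and 7 lower, with a median of -0.11 and Tgfbr3 at -2.91. Of 19 tendon and cartilage type genes 4 were higher and 13 lower, with a median of -2.01 and Spp1, an inflammatory matrix protein, at 6.47. Spp1 is also in the list of leukocyte genes. Of 12 complement genes 11 were lower, with a median of -3.26, and of 18 Wnt modulators 3 were higher and 11 lower, with a median of -0.85.

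Metabolic, inflammatory and replication genes also stood apart between these control libraries. Of 30 S-phase genes 27 were higher, with a median of 2.88, or 7.37-fold. Of 29 chemokines, cytokines and acute phase genes 20 were higher and 5 lower, with a median of 1.65 (1.57 to 1.75) and Cxcl2, a neutrophil attractant, at 5.74. Cxcl2 stood at 22670 CPM in the neutrophils of the control infarction library, so a part from free RNA was not excluded. Of 25 glycolysis and hypoxia genes 19 were higher and 4 lower, with a median of 1.60 and Slc16a3, a lactate transporter, at 4.71. Of 36 respiratory chain genes 17 were higher and 0 lower, with a median of 0.57, and of 23 secretory pathway genes 8 were higher and 4 lower, with a median of 0.20 and Sec61b at 1.92. The medians were -0.57 for interferon-stimulated genes, -0.52 for dissociation and immediate-early genes, -1.46 for adipocyte and lipid genes, 0.66 for mural and smooth muscle genes and 0.99 for 12 epicardial genes. Genes of other cells had medians of 2.68 for leukocyte genes, of which 12 of 16 were higher, -2.91 for endothelial genes and -3.35 for cardiomyocyte genes. At the stricter mitochondrial limit with the naming rule first written, the medians were 2.44 for the G2 and M-phase genes, -0.92 for the resident genes and 0.37 for the collagens. Median of ratios scaling shifts all log2 ratios of this comparison by 0.31, and the median over all 3956 genes was -0.12.

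Infarction was then compared with no infarction in the fibroblasts of the deletion-labelled hearts. The directions of the cell division, myofibroblast and resident lists were those of the controls: 39 of 40 G2 and M-phase genes were higher, with a median of 5.71 (5.34 to 5.89), or 52.3-fold, and 30 of 30 resident genes were lower, with a median of -1.67 (-1.69 to -1.64), or 3.19-fold. Cthrc1 was 292-fold higher, at 446 against 1.53 CPM, and Timp1 stood at 3296 against 49.3 CPM. Spp1 was higher, at 1068 against 6.69 CPM. It was not marked as possible free RNA, but it is also in the list of leukocyte genes and among the top genes of phagocyte cluster 3. Pi16 stood at 328 against 1471 CPM. Clusters 2 and 8 held 1490 and 489 of 2014 fibroblasts without infarction, and clusters 5, 8 and 2 held 907, 339 and 233 of 1479 after it.

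Among the named genes Hmmr stood at 9.32, with 2467 UMIs against 1 and the ratio computed against the floor. Mki67 stood at 9.09, Cdca3 at 7.58, Spc24 at 7.35 and Pclaf at 7.22. The survivin gene Birc5 stood at 7.12, the topoisomerase Top2a at 7.01 and the spindle gene Tpx2 at 6.50. Without doublet removal Hmmr stood at 4.76, Mki67 at 4.07, Top2a at 2.69 and the median of the G2 and M-phase genes at 3.75. The lowest were Angptl7 at -4.00, the clock gene Npas2 at -3.96, Efhd1 at -3.77, the adhesion molecule Lsamp at -3.51, Ces1d at -3.50, Col4a3 at -3.45, Angptl1 at -3.41, Inmt at -3.33, Col4a4 at -3.16 and Nrxn2 at -3.16.

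Of 30 myofibroblast and contractile genes 21 were higher and 4 lower in the deletion-labelled infarction library, with a median of 1.28 (1.23 to 1.33), or 2.42-fold, that was 1.91 without possible free RNA; Tnc stood at 432 against 5.595 CPM. Of 17 collagens 6 were higher and 6 lower, with a median of -0.33; Col1a1 stood at 1.20 and Col6a2 at -1.11. Of 20 genes of collagen processing 11 were higher and 1 lower, with a median of 0.80 and Lox at 4.95. The medians were 0.19 for matricellular genes, of which 11 were higher and 10 lower, 0.04 for TGF-beta genes, -1.22 for 18 tendon and cartilage type genes, -1.004 for Wnt modulators and -1.37 for complement genes. Of 30 S-phase genes 27 were higher, with a median of 2.17. Of 29 chemokines, cytokines and acute phase genes 21 were higher and 3 lower, with a median of 1.33. Of 25 glycolysis and hypoxia genes 17 were higher and 3 lower, with a median of 1.34, and of 23 secretory pathway genes 12 were higher and 1 lower, with a median of 0.71 and Manf at 1.64. The medians were 0.22 for respiratory chain genes, -0.95 for interferon-stimulated genes, of which 21 of 31 were lower, -1.40 for adipocyte and lipid genes, -0.00023 for mural and smooth muscle genes and 0.07 for 7 epicardial genes. The dissociation and immediate-early genes had a median of -0.15 that was 0.065 with median of ratios scaling and 0.23 with the mean of CPM per cell. Leukocyte, endothelial and cardiomyocyte genes had medians of 2.81, -2.57 and -2.92. Scaling by median of ratios shifts this comparison by 0.22 on the log2 scale, and the median over all 3616 genes was -0.05. At the stricter mitochondrial limit with the naming rule first written, the G2 and M-phase median was 0.76, the myofibroblast median 0.56 and the collagen median 0.30.

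The difference between the genotype log2 ratios with and without infarction was computed for single fibroblast genes as the ratio after infarction minus that without. It was highest for Apod at 4.49 (4.24 to 4.79), Tnxb at 3.97 (3.83 to 4.10), Clec3b at 3.63, Mmp3 at 3.57 and Abca8b at 3.25. It was lowest for BC004004 at -1.66, Id3 at -1.30, Sox4 at -1.22 and Fdps, an enzyme of the mevalonate pathway, at -1.09. Mmp3 stood at 203 and 8.39 CPM without infarction and at 193 and 94.8 CPM after it, control first.

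Mononuclear phagocytes were compared between genotypes with 539 and 398 cells without infarction and 2823 and 2384 after it, control first. Without infarction 14 of 21 monocyte and recruited macrophage genes were higher in the deletion-labelled library and 0 lower, with a median log2 ratio of 1.51 (0.89 to 1.60), and 9 of the 21 were marked as possible free RNA. Monocyte cluster 27, with Ear2 at its top, held 17 of the control and 43 of the deletion-labelled phagocytes, and cluster 14, with Lyve1, held 510 and 343. Plac8, a monocyte gene, was 7.18-fold higher, at 132 against 18.4 CPM, and H60b, a ligand of the NK cell receptor NKG2D, was 14.4-fold higher. Fkbp5, a co-chaperone of the glucocorticoid receptor, was 10.2-fold lower, at 12.4 against 126 CPM, and Retnla, a gene of alternatively activated macrophages, was 4.59-fold lower. Of 20 resident macrophage genes 4 were lower and 0 higher, with a median of -0.23 and Lyve1, a receptor of tissue macrophages, at -1.08. Fn1, Clmp and Ear2 were 4.53-fold, 3.83-fold and 3.17-fold higher, and Apold1, Vcam1 and Zc3hav1 were 3.73-fold, 2.80-fold and 2.40-fold lower. The medians were 0.01 for 10 genes of MHC class II antigen presentation, with H2-Eb1 at 4200 against 2078 CPM, -0.10 for 18 genes of lipid handling and clearance, and -0.15 for 21 inflammatory cytokines. They were 0.43 for interferon-stimulated, 0.31 for respiratory chain, 0.13 for S-phase, 0.10 for glycolysis and hypoxia, -0.06 for secretory pathway and -0.12 for dissociation and immediate-early genes. The median of 39 G2 and M-phase genes was -0.57, with 18 lower, and it was 1.91 with each library clustered alone.

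After infarction 9 of 20 resident macrophage genes were higher in deletion-labelled phagocytes and 0 lower, with a median of 0.42 (0.37 to 0.50) and Lyve1 at 1.29. Cluster 14 held 1 control and 13 deletion-labelled cells and cluster 27 held 31 and 53. Inflammatory cytokines had a median of 0.37 (0.34 to 0.43), with 11 of 23 higher and 1 lower, and the monocyte chemoattractant Ccl8 was 4.68-fold higher, at 166 against 35.5 CPM. Apoe, a lipid carrier, was 2.80-fold lower, at 2649 against 7409 CPM, and Apoc2 was 3.09-fold lower. Hal, histidine ammonia-lyase, was 73.8-fold higher, and the interferon-inducible Ifi202b had 3617 UMIs against 0 and was at least 1420-fold higher. Pira2 and Wfdc21 were 2.33-fold and 2.27-fold higher, and Marco, a scavenger receptor, Gdf3 and BC004004 were 3.00-fold, 2.56-fold and 2.49-fold lower. The medians were 0.14 for monocyte and recruited macrophage genes, 0.39 for MHC class II genes, -0.20 for lipid handling and clearance genes, 0.24 for interferon-stimulated genes and 0.25 for dissociation and immediate-early genes. They were -0.02 for S-phase, -0.08 for glycolysis and hypoxia, -0.046 for respiratory chain and -0.08 for secretory pathway genes, and 0.10 for G2 and M-phase genes, which was -0.033 with median of ratios scaling. That scaling shifts this comparison by -0.14 on the log2 scale.

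Neutrophils numbered 33 and 103 without infarction and 3402 and 3294 after it, control first. After infarction Mgst2, a glutathione transferase of membranes, was 59.6-fold lower in the deletion-labelled library, at 3.19 against 190 CPM, and Gstp3, another glutathione transferase, was 11.8-fold higher, at 97.1 against 8.24 CPM. Camp and Ngp, granule proteins of young neutrophils, were higher, with a log2 ratio of 2.66 for Camp and a 2.82-fold difference for Ngp, and Ifi27l2a, an interferon-induced gene, was 3.01-fold higher. Neutrophil clusters 1, 10 and 23 held 2986, 270 and 146 control and 2570, 546 and 178 deletion-labelled cells. Ctse and B3gnt2 were 2.77-fold and 2.45-fold higher, and Ecm1, Arhgap31, BC004004 and Gpc3 were 3.12-fold, 2.46-fold, 2.02-fold and 1.98-fold lower. Of 24 neutrophil maturation and activation genes 6 were higher and 1 lower, with a median of 0.22 (0.18 to 0.26). The medians were 0.34 for interferon-stimulated, 0.16 for dissociation and immediate-early, -0.04 for glycolysis and hypoxia, -0.14 for respiratory chain and -0.16 for secretory pathway genes. They were -0.22 for S-phase genes and -0.24 for G2 and M-phase genes. Without infarction Ngp had 114 UMIs against 0 and was at least 9.05-fold higher, which was a log2 ratio of 5.31 without doublet removal, and Cd14, a receptor for bacterial lipopolysaccharide, stood at 2.67. Ctnnb1, Anxa6 and Cd3d stood at 2.71, 2.45 and 2.39, with upper bounds of 4.04, 6.11 and 6.05. They had 192, 69 and 66 UMIs against 7, 2 and 2, and the counts of 2 took the floor. Cd3d is also among the markers of T and NK cells. Gripap1, Nktr, Zeb2, Lilr4b and Sec61a1 stood between -1.71 and -1.55. List medians without infarction were 0.05 for maturation and activation, 0.16 for interferon-stimulated, 0.35 for respiratory chain, -0.06 for glycolysis and hypoxia, -0.23 for secretory pathway and -0.07 for G2 and M-phase genes. The dissociation and immediate-early median of -0.29 was 0.040 with median of ratios scaling, which shifts this comparison by 0.33.

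Endothelial cells without infarction, 4252 control and 5115 deletion-labelled, differed between the genotypes in Zbtb16 and in the clock repressors Nr1d1 and Nr1d2. Zbtb16, a transcription factor induced by glucocorticoids, was 23.0-fold lower, at 3.64 against 83.5 CPM with a log2 ratio of -4.52 (-4.82 to -4.24), Nr1d1 was 6.33-fold lower and Nr1d2 3.76-fold lower. Respiratory chain genes were higher, 16 of 36 by at least 1.5-fold and 0 lower, with a median of 0.57 (0.54 to 0.59), and so were interferon-stimulated genes, 11 of 31, with a median of 0.45. Cluster 12, which has interferon-induced genes at its top, held 245 control and 663 deletion-labelled endothelial cells. The immediate-early gene Nr4a1 was 2.44-fold higher, the actin-binding Tmsb10 2.27-fold, Bloc1s1 2.25-fold and Smim27 2.18-fold, while Sec61a1 and Syn3 were 3.11-fold and 2.74-fold lower. Of 40 G2 and M-phase genes 35 were lower, with a median of -1.62 and Mki67 at 2.62 against 25.8 CPM, but the median was 0.24 without doublet removal. The medians were -0.25 for 16 capillary lipid handling genes, -0.21 for 14 adhesion and activation genes, -0.04 for 22 angiogenic genes, -0.11 for S-phase, 0.13 for dissociation and immediate-early, 0.11 for glycolysis and hypoxia and -0.10 for secretory pathway genes. The angiogenic median was 0.041 with CPM that leave out mitochondrial, ribosomal and haemoglobin genes.

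After infarction, with 223 control and 504 deletion-labelled endothelial cells, 11 of 16 capillary lipid handling genes were higher in the deletion-labelled library and 0 lower, with a median log2 ratio of 0.89 (0.79 to 1.04). Timp4, an inhibitor of matrix proteases, was 7.07-fold higher, Hspa1a, a heat shock protein, 7.85-fold, the clock output gene Dbp 6.29-fold and Klf9, a glucocorticoid-responsive transcription factor, 4.12-fold. Gal, a neuropeptide, was 5.09-fold lower and Pgf, a growth factor for blood vessels, 1.97-fold lower, and BC004004, Cebpzos and Exoc3l4 were 2.13-fold, 2.12-fold and 2.01-fold lower. With the mean of CPM per cell Timp4 stood at a log2 ratio of 4.17 and Gal at -1.10. Clusters 0, 4, 12 and 20, which are those of the hearts without infarction, held 9.87% (6.29 to 14.6) of control and 50% (45.6 to 54.5) of deletion-labelled endothelial cells. Jchain, an antibody component made by plasma cells, had 1212 UMIs against 0 and was at least 246-fold higher, but its log2 ratio was -0.47 with at least 500 genes per cell and -0.40 with each library clustered alone. Dissociation and immediate-early genes had a median of 0.52, with 13 of 29 higher. The medians were 0.01 for angiogenic genes, with Flt1, a receptor for VEGF, at 0.85, 0.10 for adhesion and activation genes, 0.18 for interferon-stimulated genes, -0.24 for glycolysis and hypoxia, -0.13 for respiratory chain and -0.14 for G2 and M-phase genes. The medians of 0.18 for S-phase genes and 0.088 for secretory pathway genes were -0.27 and -0.010 with the mean of CPM per cell.

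Mural cells of the deletion-labelled library without infarction, 550 against 196, were higher in contractile genes, 11 of 14 by at least 1.5-fold and 0 lower, with a median log2 ratio of 1.19 (1.11 to 1.34). The cells were spread differently over the clusters: cluster 26, with smooth muscle genes such as Myh11 at its top, held 116 deletion-labelled and 7 control cells, and cluster 15, with pericyte genes such as Rgs5, held 433 and 185. Acta2 stood at 2690 against 404 CPM and Cnn1 at 43.5 against 1.25 CPM. Tesc was 11.7-fold higher, Asb2 9.29-fold, Rbm24, an RNA-binding protein of muscle, 9.04-fold, Chchd10 7.91-fold and Fbxl22 7.89-fold, with a log2 ratio of 1.90 for Asb2 with the mean of CPM per cell. Pla2g7, a phospholipase, was 27.3-fold lower, Zbtb16 12.1-fold, Dbp 8.46-fold, Hist2h2ac 7.08-fold and Zc3hav1 4.96-fold. The medians were 0.80 for respiratory chain, 0.28 for interferon-stimulated, 0.29 for dissociation and immediate-early, 0.15 for glycolysis and hypoxia, -0.31 for secretory pathway, -0.22 for S-phase and 0.05 for 6 G2 and M-phase genes.

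After infarction, with 77 control and 173 deletion-labelled mural cells, contractile genes had a median of 0.13 (0.07 to 0.18), with 1 of 14 higher. Sorbs2 was 6.40-fold higher, the neuropeptide Nts 6.05-fold, Abca8a 4.36-fold, Dbp 4.34-fold and Igfbp3, which binds insulin-like growth factors, 4.26-fold. Ankrd1, a target of mechanical stress pathways, had 4 against 110 UMIs and was 46.5-fold lower. Lmcd1 was 4.69-fold, Bpgm 4.43-fold, Vgll3 4.25-fold and Actg2 3.81-fold lower. Bpgm is among the markers of red cells, and haemoglobin genes made up 0.573% of the control and 0.0029% of the deletion-labelled UMIs of these mural cells. Without doublet removal the log2 ratios were -2.44 for Ankrd1, -1.22 for Vgll3, 0.97 for Igfbp3 and 0.50 for Actg2. Clusters 15 and 26, the clusters of hearts without infarction, held 18.2% of control and 46.8% of deletion-labelled mural cells. Of 30 G2 and M-phase genes 21 were lower, with a median of -1.10 that was -0.04 without doublet removal, and 13 of 26 S-phase genes were higher, with a median of 0.56. The medians were 0.47 for interferon-stimulated, 0.21 for dissociation and immediate-early, 0.16 for respiratory chain, -0.33 for glycolysis and hypoxia and -0.29 for secretory pathway genes, and median of ratios scaling shifts this comparison by -0.13.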

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

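Of the tests in this part, those of mixed tissue, of the deletion on top of mixed tissue and of the deletion within fibroblasts alone were chosen after the result was seen, and the test of the daily clock uses a gene group chosen after the lower Nr1d1 was seen but before the values of that group were. Genotype log2 ratios without and with infarction had opposite directions, with both counting intervals away from 0, in 19 pairs of list and class. A list measured in several classes counts once per class. The same held for 6 of the genes given in the report for the difference of these ratios. With 1 library per group the difference was not tested, and genotype cannot be told apart from other differences between libraries. In each pair below the log2 ratio of the deletion-labelled over the control library after infarction comes first and that without infarction second.

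In fibroblasts complement genes stood at 1.47 and -0.24, fibrillar and network collagens at 0.27 and -0.18, and matricellular and glycoprotein matrix genes at 0.43 and -0.10. TGF-beta ligands, receptors and targets stood at 0.045 and -0.12, and collagen processing and cross-linking genes at 0.032 and -0.084. Respiratory chain genes stood at -0.044 and 0.41, and mural and smooth muscle genes at -0.43 and 0.32. The opposite direction is lost with median of ratios scaling for TGF-beta genes, at -0.0081 after infarction, and for collagen processing, at -0.021, which is -0.088 with the mean of CPM per cell. It is lost with at most 10% mitochondrial UMIs together with the first naming rule for these 2 lists, at -0.15 and -0.20, for collagens, at -0.44, and for matricellular genes, at -0.24, and in the activated fibroblast cluster alone for respiratory chain genes, at 0.040. Among single fibroblast genes the matrix protein Tnxb stood at 3.37 and -0.60, the transporter Abca8b at 3.07 and -0.17, and BC004004 at -1.52 and 0.14. Id3 stood at -0.54 and 0.75, Sox4 at -0.23 and 0.99, and Fdps at -0.41 and 0.68.

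In endothelial cells capillary lipid handling genes stood at 0.89 and -0.25, glycolysis and hypoxia genes at -0.24 and 0.11, respiratory chain genes at -0.13 and 0.57, and secretory pathway genes at 0.088 and -0.098. The value of 0.088 lies between -0.041 and -0.010 in 6 of the settings: with the mean of CPM per cell, without doublet removal, at most 10% mitochondrial UMIs under both naming rules, resolution 0.5 and each library clustered alone. In mononuclear phagocytes resident macrophage genes stood at 0.42 and -0.23, inflammatory cytokines at 0.37 and -0.15, and dissociation and immediate-early genes at 0.25 and -0.12. G2 and M-phase genes stood at 0.10 and -0.57 there, where 0.10 turns to -0.033 with median of ratios scaling and -0.57 to 1.91 with each library clustered alone, glycolysis and hypoxia genes at -0.077 and 0.095, and respiratory chain genes at -0.046 and 0.31. In neutrophils dissociation and immediate-early genes stood at 0.16 and -0.29, the latter 0.040 with median of ratios scaling, and respiratory chain genes at -0.14 and 0.35. Without infarction the respiratory chain median was thus above 0 in fibroblasts and also in each of these classes, which are not the target of the deletion.

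The 2 added sequences carried a signal that no comparison of the report uses. eGFP, a fluorescent reporter that the genotype labels do not mention, stood in fibroblasts at 628 CPM in the control and 356 CPM in the deletion-labelled library without infarction, and at 1372 and 700 CPM after it. MerCreMer, the tamoxifen-inducible Cre, stood at 8.43 and 3.45 CPM without infarction and at 0.695 and 0.905 CPM after it. After thinning, eGFP was found in 38.8%, 20.2%, 46.8% and 27.4% of fibroblasts and in 4.77%, 3.12%, 3.63% and 3.58% of endothelial cells.

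The higher resident fibroblast genes in deletion-labelled fibroblasts after infarction are consistent with a larger part of uninjured-type tissue in that library, since 50% of its endothelial cells against 9.87% of the control ones lie in clusters of hearts without infarction. An effect of the deletion on fibroblasts on top of mixed tissue cannot be told apart from its absence: the odds ratio of fibroblasts over that of endothelial cells was 2.21 (1.003 to 5.14), but endothelial over mural cells, neither of them the target of the deletion, gave 2.31 (1.02 to 5.125). Fibroblasts over mural cells gave 5.09 (2.04 to 13.2), and with the 50% cutoff the values were 2.11 (1.15 to 3.84) over endothelial and 4.87 (2.26 to 10.2) over mural cells, each with a lower bound above 1 and under 2.31. The rule first written asked only for a lower bound above 1, which 1.003 met. The requirement that the lower bound exceed the endothelial over mural ratio was added after the value had been seen. Free RNA would reach phagocytes too, where the CPM difference of these genes was a median of 0.501% of that in fibroblasts, too little to account for it.

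Nr1d1, Nr1d2 and Dbp were lower in the deletion-labelled library without infarction beyond fibroblasts, and their median log2 ratio in endothelial cells was -2.66. An effect of the deletion within fibroblasts alone is therefore not enough to account for it. Collection of the hearts at different phases of the daily clock would set genes of the Arntl group against them, and that group had a median of 0.16 in endothelial cells, the class named for the test, under the 0.58 required. It was 0.61 in mural cells and 0.42 in fibroblasts, with 4 of 5 genes above 0 in each, and 0.25 in phagocytes and -0.25 in B cells. With medians of 3 to 5 genes on both sides of the limit, a difference in phase cannot be told apart from its absence.

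Gm10260, Gm11361 and Ifi202b, chosen after their values were seen, were near absent in 1 library of a genotype comparison in every class measured. Alleles carried along with the targeted gene could produce such a pattern, but 3 of the 3 lie more than 20 Mb from Tcf21 or on another chromosome. Gm10260 and Gm11361 were lower in the deletion-labelled library in both genotype comparisons, while Ifi202b had 6 control and 2 deletion-labelled UMIs without infarction, with a log2 interval from -5.48 to 0.34 that includes 0, and 0 and 5339 UMIs after it, the opposite direction. With at least 30 UMIs required in both comparisons 0 of the 3 went the other way. That count decides nothing, since Ifi202b has too few UMIs to be counted and Gm10260 was chosen in both comparisons. Without infarction Gm10260 was lower in each of 6 classes, with a median log2 ratio of -5.95, and Gm11361 in each of 5, at -4.73. Both were chosen for differing the same way in every class measured, so this was fixed by the choice and is no test. For these 2 features it shows only that the difference is not confined to fibroblasts. An effect of the deletion that reaches other classes cannot be told apart from an untested difference in strain background.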

How the results depend on the processing

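The activated fibroblast cluster alone and the first naming rule were chosen after the result was seen, and the other alternatives before. Log2 ratios compare the deletion-labelled with the control library (genotype) or infarction with no infarction; the cause was not tested for any value in this part. In the settings chosen before, the median of resident genes lay between 0.073 and 0.16 without and between 1.40 and 1.90 with infarction, and Tcf21 was higher in the deletion-labelled library without infarction in the 9 settings chosen before, between 0.58 and 0.69. These ranges leave out the naming rule first written, whose values after infarction are given below. Of the list values outside the main ones, 1529 stayed within their interval, 352 moved outside it and 38 turned. For single genes outside the main ones these numbers were 1490, 227 and 3. Among the main results they were 69, 29 and 1 for lists and 18, 2 and 1 for single genes. For shares of cells, where turning was not counted, 25 stayed and 15 moved among the main ones, and 108 and 116 among the others. Only a change of direction from an interval away from 0 was counted as turned, so a value counted as moved can also have changed direction.

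With median of ratios scaling the genotype medians in fibroblasts were 0.13 for resident genes and -0.14 for collagens without infarction, and 1.40, -0.33 and 0.22 for resident, myofibroblast and collagen genes with it. The infarction medians of myofibroblast genes were 1.86 in controls and 1.49 in deletion-labelled hearts. The medians that turned were collagen processing at -0.021, TGF-beta genes at -0.0081 and phagocyte G2 and M-phase genes at -0.033 after infarction, neutrophil immediate-early genes at 0.040 without it, and fibroblast immediate-early genes at 0.065 for infarction in deletion-labelled hearts. With CPM that leave out mitochondrial, ribosomal and haemoglobin genes, resident, myofibroblast and collagen medians without infarction were 0.16, 0.036 and -0.11, the infarction medians of myofibroblast genes were 1.75 and 1.38, and endothelial angiogenic genes turned to 0.041.

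With the mean of CPM per cell resident genes stood at 0.081 without and 1.90 with infarction, myofibroblast genes at -0.46, Tcf21 at 0.98 after infarction, and myofibroblast genes at 1.78 for infarction in controls. Collagen processing turned to -0.088, endothelial S-phase genes to -0.27, endothelial secretory genes to -0.010 and fibroblast immediate-early genes to 0.23. Without doublet removal resident genes without infarction stood at 0.073, collagens with it at 0.30 and myofibroblast genes for infarction in deletion-labelled hearts at 1.21; endothelial G2 and M-phase genes turned to 0.24, endothelial secretory genes to -0.022 and mural Actg2 to 0.50. Without possible free RNA myofibroblast genes stood at -0.30 without and -0.19 with infarction and at 1.91 for infarction in deletion-labelled hearts, and adipocyte genes turned to -0.0044.

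With each library clustered alone myofibroblast genes after infarction stood at -0.33, and cardiomyocyte genes in fibroblasts turned to -1.47, phagocyte G2 and M-phase genes to 1.91, endothelial secretory genes to -0.030 and Jchain to -0.40. With at least 500 genes the fibroblast share without infarction in the deletion-labelled library was 20.7% and Jchain stood at -0.47. Endothelial secretory genes turned to -0.041 with at most 10% mitochondrial UMIs, under both naming rules, and to -0.016 at resolution 0.5. Among named non-immune cells the fibroblast shares were 29.6%, 25.9%, 74.6% and 67.3%. Fibroblasts with a Tcf21 UMI were 53.9%, 70.8%, 37.4% and 39.6% without thinning and 8.15%, 13.1%, 2.26% and 4.36% at 1000 UMIs.

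With the first naming rule at that mitochondrial limit the fibroblast shares after infarction were 0.299% and 6.06%. The genotype values after infarction were 0.69 for resident genes, -0.72 for myofibroblast genes and 0.20 for Tcf21, and turned to -0.44 for collagens, -0.20 for collagen processing, -0.24 for matricellular, -0.15 for TGF-beta, -0.39 for tendon-type, -0.060 for Wnt, 0.20 for epicardial, -0.082 for interferon-stimulated, -1.32 for endothelial and -0.56 for cardiomyocyte genes. For infarction in controls collagens turned to 0.37, matricellular genes to 0.83, tendon-type genes to 0.36, secretory genes to -0.14 and cardiomyocyte genes to 0.45. For infarction in deletion-labelled hearts myofibroblast genes stood at 0.56, and collagens turned to 0.30, complement genes to 0.092, immediate-early genes to 0.13 and respiratory chain genes to -0.12. In the activated fibroblast cluster alone resident genes stood at 0.48, myofibroblast genes at -0.10 and collagens at 0.21, while Tcf21 turned to -0.037 and respiratory chain genes to 0.040.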

Other observations

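The lists of clock and glucocorticoid-induced genes in this part were chosen after the result was seen, and no explanation is tested on them here. Clock genes that peak with Nr1d1 had median log2 ratios of the deletion-labelled over the control library without infarction of -0.46 in fibroblasts, -1.20 in endothelial cells, -1.83 in mural cells, -0.10 in phagocytes, with 5 above and 5 below 0, and -0.35 in B cells, with 3 on each side. After infarction they stood at 0.72, 1.40, 0.96 and 0.56 in the first 4 of these classes, -0.38 in B cells and 0.093 in neutrophils. Genes of the Arntl group, which peak opposite to them, stood at 0.42 in fibroblasts, 0.16 in endothelial cells, 0.61 in mural cells, 0.25 in phagocytes and -0.25 in B cells without infarction. They stood at 0.10, 0.22, -0.079, 0.15 and -0.38 in that order after it, and at 0.13 in neutrophils. Genes induced by glucocorticoids, the stress hormones of the adrenal gland, stood at -0.12 in fibroblasts, -0.39 in endothelial cells, -0.37 in mural cells, -0.15 in phagocytes, -0.53 in neutrophils and -0.019 in B cells without infarction, and at 0.26, 0.57, 0.53, 0.38, 0.25 and 0.36 after it.

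Gm10260, on chromosome 13, had 2682 UMIs in the control and 22 in the deletion-labelled library without infarction, and 8914 and 73 after it. Gm11361, also on chromosome 13, had 1452 and 51 UMIs without infarction and 1006 and 58 after it. Haemoglobin genes made up 0.126% and 0.625% of UMIs without infarction and 0.0113% and 0.309% after it, control first.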
